A study of Mus musculus with 2 samples.

How the data were processed

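H3K4me2, the dimethylated form of lysine 4 on histone H3 that marks promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in the forebrain of B6NCrl mouse embryos at embryonic day 15.5. Per the labels, the series holds 1 group of 2 biological replicates, each a pool of tissue from both sexes: 78 embryos in replicate 1 and 62 in replicate 2, with a library size range of 300 to 500. No condition was contrasted, so the comparisons were those between the replicates, between peak lists, and between gene groups or sequence classes within the lists.

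The authors deposited 4 peak lists on mm10: 1 per replicate, 1 called on both replicates together (the pooled list) and 1 of replicated peaks, which per the deposited file descriptions was derived from the other 3. The fold enrichment of each peak is a ratio over control in the deposited lists, the peak's own value by the definition of the format, and the authors' fold was used only to rank or filter peaks within its own list. The deposited lists also give each peak's p and q as −log10 values. The lowest −log10 p was 2.03 in replicate 1, 2.02 in replicate 2, 2.00 in the pooled list and 2.21 in the replicated list. The summit is given as a distance in bases from the start of the peak. The aligner, the peak caller and the rule by which a peak counted as replicated are not given in the sources used here. Control libraries, alignments and signal tracks were not analysed here. The lists carry no read counts, so the depth of either library is unknown, and a region without a peak may lie below what that depth could detect.

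All 34001 replicated peaks on chromosomes 1 to 19, X and Y had the same position and values in the pooled list, and they formed the main list. Peaks on unplaced scaffolds (12 to 15 per list) were left out of everything but the total counts. No peak ran past the end of a chromosome of the reference, and no summit lay outside its peak. Genes and transcription start sites (TSS) were those of GENCODE release M21 on GRCm38, the assembly that mm10 names: 21938 protein-coding genes, and 111646 TSS of protein-coding or lncRNA transcripts. Coordinates are given 1-based on that build.

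A promoter counted as occupied when a peak overlapped the 1 kb on either side of any annotated TSS of the gene. A peak was placed by its summit, first at a TSS within 1 kb, then in another exon, an intron or between genes. Peaks of the replicates counted as shared when the overlap reached 50% of either interval, and the same was done with 100 random placements of the other list within its chromosomes. Breadth was the number of bases covered by peaks within 5 kb of the gene's 5' end. Distal peaks, with a summit more than 1 kb from every TSS, were assigned to the nearest protein-coding TSS within 100 kb. Domains were replicated peaks merged when at most 1 kb apart, and the longest 5% were called broad. A promoter was CpG-rich when the 500 bases on either side of the gene's 5' end had a CpG observed/expected ratio of at least 0.6 and a GC content of at least 50%. Its occupancy still counted a peak at any annotated TSS of the gene, so the peak may lie at another start site than the one classed. Distal sequence was searched on both strands for 16 short words, in 1000-base windows around summits and in windows 5 kb away outside every peak. The ratio of the shares was divided by the median ratio over all rearrangements of the word's bases with as many CpG. The percentile among the rearrangements was the planned measure, and the 95% level used to count words was set with the computation.

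The 26 gene lists, the tests, the alternatives and the rule for the genes named were fixed before the data were examined. Of the fixed symbols, 17 of 18 erythroid and 23 of 25 imprinted ones matched a protein-coding gene, and all symbols of the other lists did. Pax6, Six3, Mafb, Tal1 and Igf2 each belonged to a pair of lists. Occupancy and broad domains were tested with two-sided Fisher's exact tests. Breadth and distal peaks were set against 10000 random lists of the same size, for distal peaks matched on deciles of the territory nearest each gene. The random lists were drawn with replacement, and the two-sided p was the list's percentile among them, at smallest 0.0002. These are called permutation tests below, although only the comparison of posterior with telencephalic factors permuted genes between lists. All p-values were adjusted by the Benjamini-Hochberg method over the lists tested (26, and for breadth the 22 with at least 5 occupied members), and 0.05 was the threshold. Genes are not independent replicates, so these p-values describe the gene lists in these 2 libraries and not variation between animals. The rule named, for each list, the 3 members with most covered bases and the first 3 without a promoter peak, the genes at the 10 longest domains, the 10 genes with most distal peaks, the 5 strongest peaks and, per replicate, the 5 genes of highest fold called in that replicate alone. Genes named outside it are said to be so.

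The procedures were first tested on simulated data. With 200 lists of 25 genes drawn from the 21938 genes, of which some were changed, the occupancy test called 98% of the changed and 3% of the unchanged lists. The figures were 92% and 0% for breadth, 91% and 3% for distal peaks, and 100% and 1% for broad domains. The planted changes were large, so these figures do not tell how often smaller differences or shorter lists would be called. The overlap step recovered 100% of the planted shared peaks among 20000. Both planted words stood above every rearrangement, but 2 of 14 other words also passed the 95% level, so passing it is weak evidence for a word. Alternatives were each replicate's list alone, the pooled list, the replicated peaks above the median fold, other windows, overlaps and distances, promoters split by CpG content, other backgrounds and other control windows. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and random steps used seed 1.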

Results

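H3K4me2 was mapped in forebrain tissue of mouse embryos at embryonic day 15.5, a stage at which cortical and striatal neurons are being produced, in 2 biological replicates pooled from 78 and 62 embryos. Replicate 1 gave 42147 peaks covering 45.2 Mb and replicate 2 gave 43362 peaks covering 46.5 Mb (mean 42754.5 ± 859 peaks, SD, n = 2). The pooled list held 45503 peaks over 52.2 Mb, and the replicated list, used below unless another is named, held 34013 peaks over 49.1 Mb. The median peak width was 695 ± 11.3 bases in the replicates (SD, n = 2), 704 bases in the pooled list and 1064 bases in the replicated list. The depth of the libraries is unknown, since the lists give no read counts, and the design has no second condition. Values written as mean ± SD are over the 2 replicates' own lists.

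The strongest replicated peaks stood at promoters. The highest fold over control was 61.2 at Tbc1d1, a Rab GTPase-activating protein (chromosome 5, 64158637 to 64161974), followed by 59.4 at Galnt3, which starts mucin-type O-glycosylation (chromosome 2, 66123631 to 66125519). Gcnt4 (58.9, chromosome 13), Esyt1 (58.4, chromosome 10) and Ppargc1b, a coactivator of mitochondrial genes (57.2, chromosome 18), came next. All 5 summits lay within 1 kb of a TSS.

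The replicates were compared peak by peak. The strong peaks were found in both: in the highest 4 of 10 equal ranks by fold, 100% of the peaks of either replicate were shared with the other, and the fifth rank was shared at 99.98% in replicate 1 and 99.93% in replicate 2. Sharing fell to 38.6% and 30.9% in the lowest rank. The peaks of the highest rank were mostly promoter peaks, with 88.4% (replicate 1) and 89.1% (replicate 2) of summits at a TSS and median widths of 1960.5 and 2007 bases. In the lowest rank 16.3% and 15.2% lay at a TSS, and the median widths were 230 and 232 bases. Over the whole lists 81.7% of replicate 1 peaks and 78.1% of replicate 2 peaks were shared, against at most 3.03% and 2.95% in 100 random placements. Their mean was 79.9 ± 2.55% (SD, n = 2, the 2 directions of the same comparison and not separate measurements). With a 1-base overlap the shares were 84.7% and 81.1%, and with 50% of both intervals 69.5% and 67.6%.

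**Figure D1:**
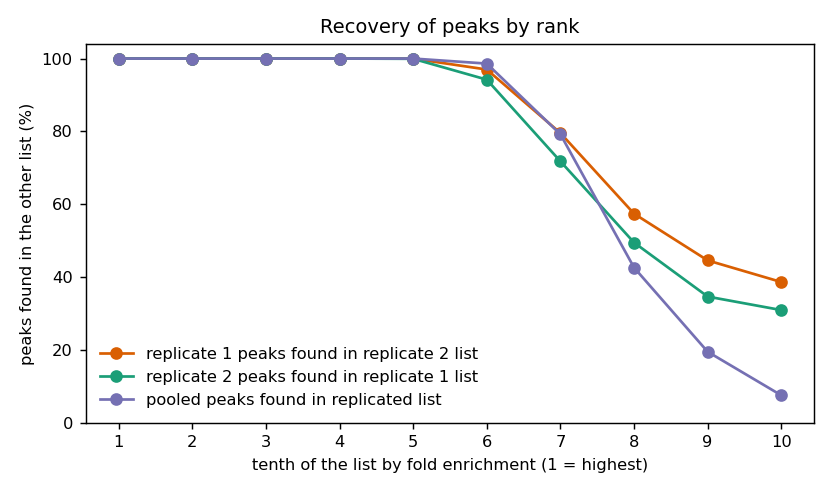
Each point is 1 of 10 equal ranks of a list by its own fold enrichment (x axis, 1 = highest), and the y axis is the percentage of its peaks found in the other list: replicate 1 in replicate 2 (orange), replicate 2 in replicate 1 (green) and pooled in replicated (purple). Sharing was 100% in ranks 1 to 4 and ended at 38.6%, 30.9% and 7.54% in rank 10.

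Of the pooled peaks on chromosomes, 74.7% were in the replicated list. These had a median width of 1065 bases and a median fold of 12.7, and 51.7% lay at a TSS. The 11487 pooled peaks left out had a median width of 240 bases and a median fold of 2.60, and 13.3% lay at a TSS.

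Promoter regions held the largest share of peaks. In the replicated list 51.7% of summits lay within 1 kb of a TSS, against a median of 4.995% and at most 5.31% in 100 random placements, and 4.43% lay in other exons, against at most 3.53%. Introns held 23.3% and intergenic sequence 20.6%, under the lowest random values of 39.3% and 51.0%. In the replicates' own lists the TSS share was 46.5 ± 0.933% (SD, n = 2), the intronic share 28.3 ± 0.503% and the intergenic share 20.3 ± 0.348%. TSS peaks were also wider (median 1721 bases) than intronic (619 bases) or intergenic peaks (657.5 bases).

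A peak stood at the promoter of 14561 of 21938 protein-coding genes (66.4%; 66.6 ± 0.226% in the replicates, SD, n = 2). Of 9740 genes with a CpG-rich 5' end 98.8% were occupied at any TSS (98.9 ± 0.0726%), and of 12198 with a CpG-poor 5' end 40.5% were (40.9 ± 0.348%). Of 13374 lncRNA genes 24.96% had a promoter peak, and of the 10536 whose TSS lay more than 2 kb from any protein-coding TSS, 11.6% did. Chromosome X carried 6.84 ± 0.0537 peaks per Mb (SD, n = 2) and autosomes 16.9 ± 0.352, and 51.4 ± 0.0746% of X-linked against 67.9 ± 0.241% of autosomal protein-coding genes were occupied. Single autosomes had from 12.1 to 26.2 peaks per Mb and from 54.8% (chromosome 7) to 81.96% (chromosome 12) of their genes occupied, so in the share of genes chromosome 7 lay close to X. X also holds fewer protein-coding genes, 5.54 per Mb against 8.45 on autosomes. Chromosome 12, with 5.35 genes per Mb, nevertheless had 14.3 (replicate 1) and 14.8 (replicate 2) peaks per Mb. Chromosome 18, with 5.66 genes per Mb, had 14.97 and 15.5. These values argue against gene density alone giving the low peak density of X, and no other cause was tested.

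Gene groups were then compared by promoter occupancy. Telencephalic, neural progenitor and neuronal groups were occupied almost in full. All 20 telencephalic patterning factors had a promoter peak, among them Otx1, Nr2f1 and Zic1, transcription factors that pattern the forebrain (adjusted p = 0.000854, two-sided Fisher's exact test, as for each list in this comparison). So did all 34 genes of the GABAergic and ventral telencephalic lineage, such as Dlx1 and the vesicular GABA transporter gene Slc32a1 (adjusted exact p = 4.69e-06), all 25 of radial glia and neural stem cells, such as Sox1, Sox2 and the Notch ligand gene Dll1 (adjusted p = 0.000125), and all 30 pan-neuronal genes, such as Insm1, Celf4 and Scrt1 (adjusted p = 1.80e-05). Of the 33 genes of the cortical glutamatergic lineage 32 were occupied (adjusted exact p = 0.000125). The exception was Neurod4, a proneural bHLH gene, with a promoter peak in replicate 2 alone.

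A further 4 groups were occupied more often than other genes. They were 77 of 80 ribosomal protein genes (adjusted exact p = 6.11e-10), 17 of 17 activity-dependent early response genes such as Nr4a3, Egr3 and Ier2 (adjusted p = 0.00228), 21 of 23 imprinted genes (adjusted p = 0.0187) and 24 of 26 midbrain, hindbrain and spinal cord factors (adjusted p = 0.00490). The 3 ribosomal genes without a promoter peak were Rpl10l, Rpl39l and Rpl3l, paralogs with tissue-restricted expression. Ndn and Rtl1 were the imprinted genes without one. Phox2b and Evx1 were the posterior factors without one. Mafb, which is also on the GABAergic list, Egr2 and Gata2 had 6913, 4298 and 4276 bases covered within 5 kb of the TSS (6197.5 ± 281, 4208.5 ± 61.5 and 3954 ± 35.4 in the replicates, SD, n = 2). Diencephalic and hypothalamic factors were occupied at 19 of 22 genes, which missed the threshold (adjusted exact p = 0.0801); with replicate 2 alone it was 90.9% (adjusted p = 0.0176) and with a TSS window of 2 kb 95.5% (adjusted p = 0.00398). Pomc, Avp and Dbx1 were the members without a promoter peak in the replicated list, while the list of replicate 2 had one at 20 of the 22 genes. With the 5' end as the only TSS, posterior factors (76.9%, adjusted exact p = 0.196) and imprinted genes (78.3%, adjusted p = 0.177) lost their calls, and with replicated peaks above the median fold alone imprinted genes lost theirs (78.3%, adjusted p = 0.164) and the posterior factors fell to 50%, on the lower side (adjusted p = 0.355).

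Genes of microglia, leukocytes and erythroid cells and of other tissues were occupied less often than other genes. Of 21 microglia and leukocyte genes 3 had a promoter peak (adjusted exact p = 4.69e-06): Cd14 and P2ry12 were covered over 1380 and 344 bases, Runx1 had its peak at another start site than the 5' end, and Cx3cr1, Csf1r and Tmem119, markers of microglia, had none. The liver group had 3 of 20 (adjusted exact p = 1.05e-05), with no peak at Alb, Afp or Apoa2 and peaks at Apoh, Apoa1 and Foxa3; with either replicate alone 2 were occupied. Erythroid genes had 5 of 17 (adjusted exact p = 0.00483), with peaks at Tal1, Epor and Klf1 and none at the globin genes Hba-a1, Hba-a2 and Hba-x. Gut, lung and kidney epithelium had 5 of 20 (adjusted exact p = 0.000372), heart 8 of 20 (adjusted p = 0.0233) and skeletal muscle 6 of 16 (adjusted p = 0.0370). The heart call was lost with replicate 2 alone (45.0%, adjusted exact p = 0.0677), the pooled list (adjusted p = 0.0695) and a TSS window of 2 kb (adjusted p = 0.0691). The muscle call was lost with that window (43.75%, adjusted exact p = 0.0748) and with the 5' end as the only TSS (37.5%, as in the main setting, adjusted p = 0.0905). Among CpG-poor promoters alone, erythroid (25%, adjusted exact p = 0.401), gut, lung and kidney (22.2%, adjusted p = 0.205), heart (35.3%, adjusted p = 0.874) and muscle genes (28.6%, adjusted p = 0.509) lost their calls, while microglial and liver genes kept theirs. In the replicated list Myh6, Nppa and Nppb of the heart, Myf5, Myog and Acta1 of muscle, and Cdx2, Vil1 and Fabp2 of gut were without a promoter peak, while Gata6, Myl3, Tnni3, Mylpf, Myod1, Ckm, Sftpc, Foxa1 and Nphs1 had one. The list of replicate 2 had more, with 9 of 20 heart and 7 of 20 gut, lung and kidney genes occupied.

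Germline genes were occupied at 5 of 20 (adjusted exact p = 0.000372), with peaks at Gdf9, Tdrd1 and Dazl and none at Ddx4, Sycp1 or Sycp3, the last a pair of synaptonemal complex genes; among CpG-poor promoters alone the call was lost (15.4%, adjusted exact p = 0.128). Among the large clustered families, 3 of 1134 olfactory receptor genes (Olfr94, Olfr658 and Olfr1033; the p was too small to be represented) and 1 of 328 vomeronasal receptor genes (Vmn1r4; adjusted exact p = 3.63e-154) had a promoter peak. Keratins and keratin-associated proteins had 11 of 110 (adjusted exact p = 4.04e-34), among them Krt10, Krt18 and Krt1. Clustered protocadherins, cell-adhesion genes with alternative first exons, had 15 of 56 (adjusted exact p = 8.75e-09), with most bases covered at Pcdhgc4, Pcdhgc5 and Pcdhgc3. At least 50% of the sequence sampled recurred elsewhere on the chromosomes for 34.5% of vomeronasal and 3.35% of olfactory receptor promoters, against 7.12% of all protein-coding genes and 2 of the 17 erythroid ones. Hox genes, which pattern the body axis behind the forebrain, were occupied at 19 of 39 (adjusted exact p = 0.0342). That call was lost with either replicate alone (53.8% in both; adjusted exact p = 0.107 for replicate 2 and 0.148 for replicate 1) with the pooled list (59.0%, adjusted p = 0.362), with a TSS window of 2 kb (56.4%, adjusted p = 0.203), with the 5' end as the only TSS (46.2%, adjusted p = 0.0653) and among CpG-poor promoters alone (6 of 15, adjusted p = 1). Hoxa7 (1502 bases, 1224 ± 327 in the replicates, SD, n = 2), Hoxd1 (1353, 1309 ± 15.6) and Hoxd13 (1341, 1198 ± 109) had most bases covered, and Hoxa2, Hoxa3 and Hoxa6 were without a promoter peak.

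The remaining groups did not pass the test. They were oligodendrocyte genes (9 of 16, adjusted exact p = 0.467), astrocyte genes (10 of 12, adjusted p = 0.406), endothelium and pericytes (13 of 20, adjusted p = 1) and meninges and choroid plexus (12 of 18, adjusted p = 1). Within them, Olig2, Sox8 and Pdgfra of the oligodendrocyte lineage were occupied, and Plp1, Mog and Sox10 were not. Myelin genes went both ways, since Mbp and Cnp, named after their values were seen, had promoter peaks. Fgfr3, Slc1a2 and Sparcl1 of astrocytes were occupied, and Gfap and S100b were not. Mfsd2a, Sox18 and Kcnj8 of vessels and Foxc1, Foxj1 and Lmx1a of meninges and choroid plexus had peaks, and Pecam1, Cdh5, Tek, Ttr, Folr1 and Aqp1 had none at the promoter. Among genes with a CpG-poor 5' end alone the same 9 lists were higher as among all genes, such as pan-neuronal genes (13 of 13, adjusted exact p = 5.02e-05) and the GABAergic lineage (11 of 11, adjusted p = 0.000246). Their peak could lie at another start site, whose CpG content was not classed: Gad1 of the GABAergic list had 0 bases covered within 5 kb of its 5' end. Among CpG-rich promoters alone, where 98.8% were occupied and little room was left above, no list was higher and 2 were lower, Hox genes (13 of 24, adjusted exact p = 1.93e-14) and germline genes (3 of 7, adjusted p = 7.22e-06).

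**Figure D2:**
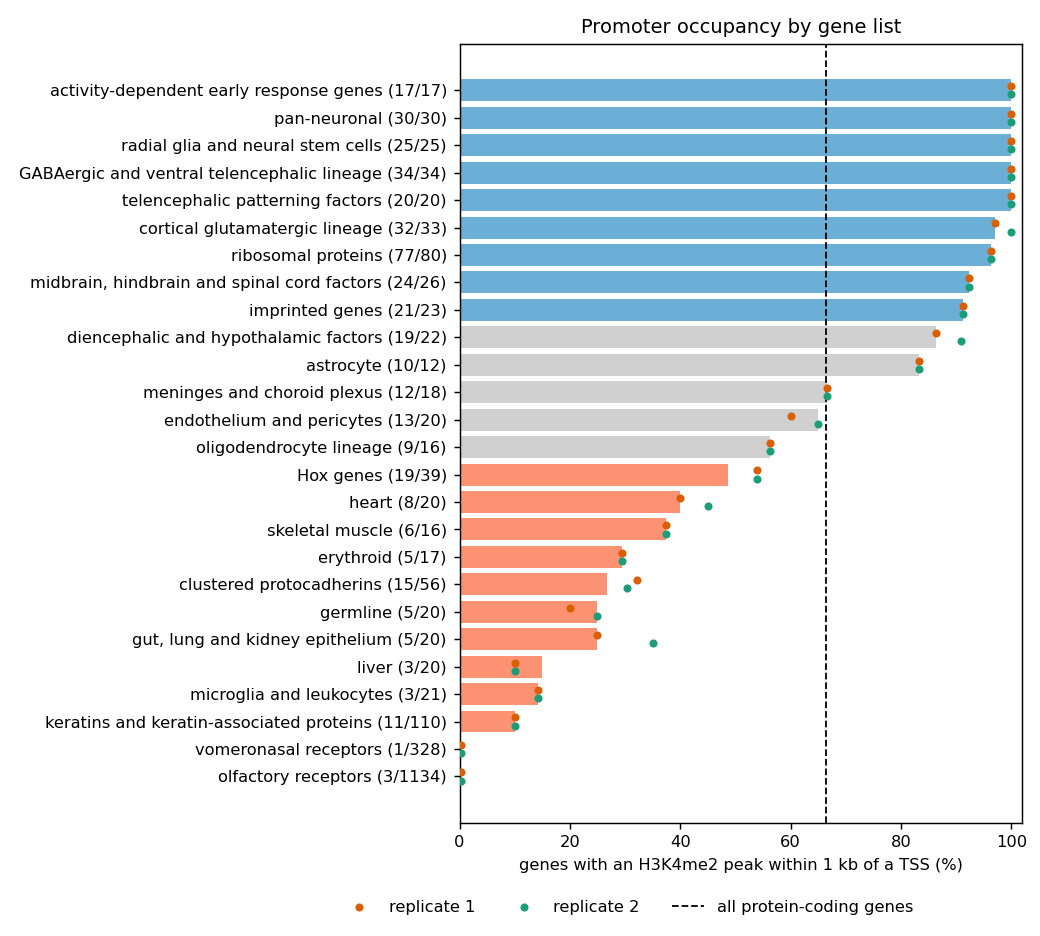
Bars give the percentage of each list's genes with an H3K4me2 peak within 1 kb of a TSS (x axis; counts after each list name), blue where higher and red where lower than other genes at an adjusted p under 0.05 and grey otherwise, with points for replicate 1 (orange) and replicate 2 (green) and a dashed line at all protein-coding genes (66.4%). The lists run from 100% for 5 lists, among them pan-neuronal genes, to 0.265% for olfactory receptors.

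Among occupied promoters, those of telencephalic, neural progenitor and neuronal genes were covered over the most bases. The median coverage within 5 kb of the TSS was 6762.5 bases for telencephalic patterning factors (6533.5 ± 43.8 in the replicates, SD, n = 2), 5822.5 for the cortical glutamatergic lineage (5577.25 ± 71.8), 5818.5 for the GABAergic lineage (5365 ± 222), 5441 for radial glia (5220 ± 416) and 5259.5 for pan-neuronal genes (4975.5 ± 60.1). Random lists of the same sizes had medians between 2398 and 2408. Meis2, a homeodomain factor of the striatum (chromosome 2, 115863064 to 116065839), and Otx1 (chromosome 11, 21994764 to 22002897) were covered over the whole window of 10001 bases. Nr2f1 had 9939 bases (9837.5 ± 121), Pou3f3 9844 (9709 ± 262), Bcl11a, which sets projection neuron identity, 9814 (9737 ± 49.5), Sox1 9663 (9118.5 ± 58.7), Slc32a1 9698 (9655 ± 185) and Insm1 9469 (9062 ± 168).

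Early response genes had a median of 4272 bases (4105 ± 83.4, SD, n = 2), led by Nr4a3 with 7694, and ribosomal protein genes 2835 (2682 ± 45.3), led by Rpl35 with 6165. Lower medians were found for clustered protocadherins (615 bases, 713 ± 53.7 in the replicates), keratins (854, 713 ± 170), Hox genes (856, 791 ± 42.4), germline genes (1060, 1075 ± 147), heart genes (1170, 1129.5 ± 140) and meninges and choroid plexus (1376, 1210 ± 116). In two-sided permutation tests against 10000 random lists, the adjusted p was 0.000489, from the smallest p they can give, for the 5 lists of the highest medians, early response genes, Hox genes, protocadherins and keratins. It was 0.0242 for ribosomal protein, 0.0355 for germline and 0.00800 for both heart and meningeal genes. Diencephalic (2168 bases, adjusted permutation p = 0.505), oligodendrocyte (2486, 0.897), astrocyte (2847, 0.426), endothelial (1900, 0.201), erythroid (1466, 0.122), muscle (1445.5, 0.0654), gut, lung and kidney (1303, 0.0654), posterior neural (2381.5, 0.924) and imprinted genes (2477, 0.897) did not pass. Gut, lung and kidney genes were called lower with replicate 2 alone (468 bases, adjusted permutation p = 0.00264) and with the pooled list (1044.5, 0.0125), muscle genes with replicate 1 alone (1231.5, 0.0494) and erythroid genes with replicated peaks above the median fold (1007, adjusted p = 0.00800). A window of 2 kb made these 3 lists, diencephalic and posterior factors lower (adjusted permutation p from 0.00165 to 0.0378), and one of 10 kb made imprinted genes higher (3752 bases, adjusted p = 0.0288). With a window of 10 kb on either side, the heart call was lost (1791.5 bases, adjusted permutation p = 0.104). With all members counted and all protein-coding genes as background, the lower calls were lost for Hox (633 bases, adjusted permutation p = 0.127), germline (0, 0.127), heart (171, 0.129) and meningeal genes (565, 0.202). Microglial, liver, olfactory and vomeronasal genes had too few occupied members for this test.

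**Figure D3:**
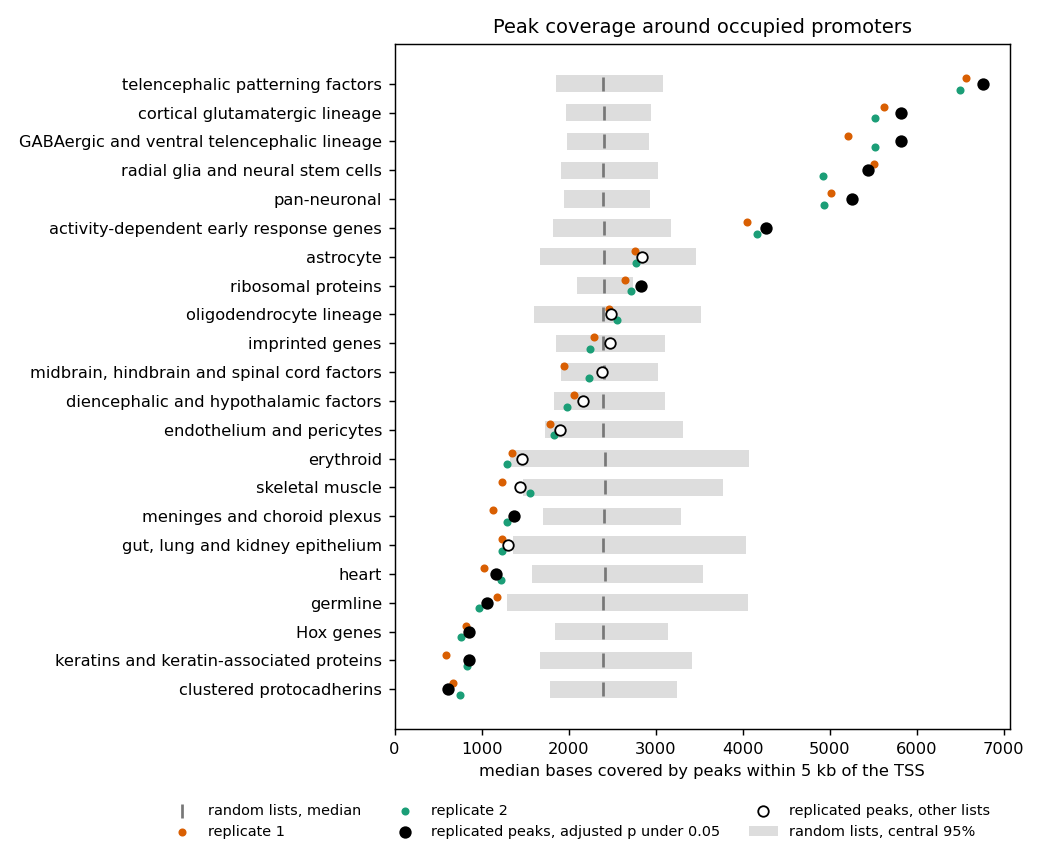
Median bases covered by peaks within 5 kb of the TSS (x axis) over the occupied members of each list, from the replicated list (black, filled where the adjusted p was under 0.05) and from replicate 1 (orange) and replicate 2 (green), with the median (line) and central 95% (grey bar) of 10000 random lists. The medians run from 615 bases for clustered protocadherins to 6762.5 for telencephalic patterning factors.

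Distal peaks were more numerous around genes of forebrain groups than around matched genes. The cortical glutamatergic lineage had 5.88 distal peaks per gene, against a median of 1.27 in random lists matched on territory (8.82 ± 0.0429 from the replicates' longer lists, SD, n = 2), telencephalic patterning factors 4.65 against 1.15 (7 ± 0.354), the GABAergic lineage 4.18 against 1.15 (6.24 ± 0.333) and pan-neuronal genes 3.63 against 1.13 (5.10 ± 0.330). Diencephalic factors had 3.09 against 0.864 (4.205 ± 0.0964). All 5 had an adjusted p of 0.000743 in two-sided permutation tests, from the smallest p they can give. Radial glia genes (3.20, adjusted permutation p = 0.00231), posterior neural factors (2.62, adjusted p = 0.00195), early response genes (2.06, adjusted p = 0.00945) and oligodendrocyte genes (1.94, adjusted p = 0.00416) were also higher. Olfactory (0.0229) and vomeronasal receptors (0.0396) were lower, both with an adjusted permutation p of 0.000743. With replicated peaks above the median fold alone, the calls for diencephalic (adjusted permutation p = 0.828) and oligodendrocyte genes (adjusted p = 0.644) were lost. With a limit of 500 kb that for early response genes was lost (adjusted permutation p = 0.144), although their own value was 2.24 per gene.

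The genes with most distal peaks were Gse1 with 31 (39.5 ± 0.707 in the replicates, SD, n = 2), Nfib with 28 (41.5 ± 2.12) and Tcf4 with 22 (36 ± 2.83). Nfib is a nuclear factor I gene of cortical progenitors and glia, and Tcf4 is a partner of proneural bHLH factors. Pbx1 and Zfhx3 had 19 each, E130114P18Rik 18, Bcor, Nfix and Zfp423 17 each, and Adgrl2 16. Of 16430 distal peaks 13637 were assigned, to 6730 genes. The lists that did not pass lay between 0.109 distal peaks per gene for keratins (adjusted permutation p = 0.0832) and 1.48 for imprinted genes (adjusted p = 0.179). Keratins were called lower with replicate 2 alone (0.136, adjusted permutation p = 0.00676), with replicate 1 alone (0.118, adjusted p = 0.00462), with the pooled list (0.182, adjusted p = 0.0433) and without matching (adjusted p = 0.000520), as were protocadherins without matching (adjusted p = 0.00189). Imprinted genes were called higher with replicate 1 alone (2.43, adjusted permutation p = 0.0436) and without matching (adjusted p = 0.0461). Among them Hox genes had 0.231 against 0.179 in random lists (adjusted permutation p = 0.930), microglial genes 0.571 against 0.524 (adjusted p = 0.994) and ribosomal protein genes 0.413 against 0.3 (adjusted p = 0.376).

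**Figure D4:**
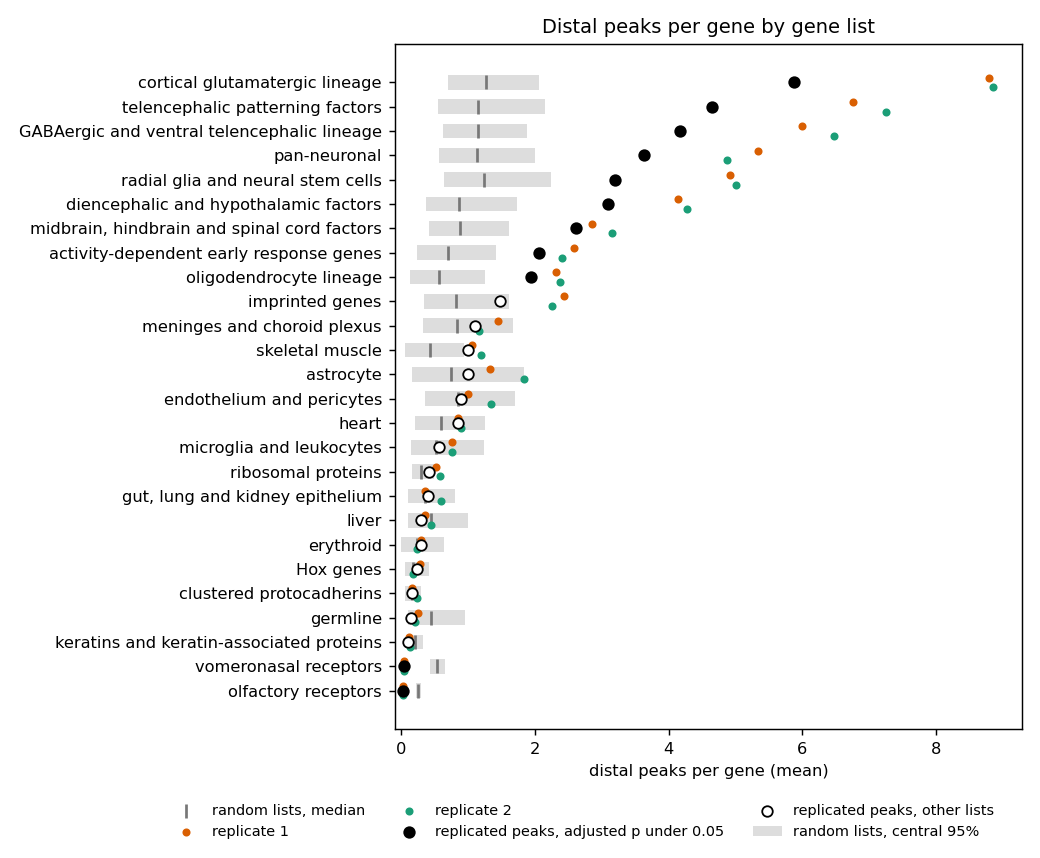
Mean number of distal peaks per gene (x axis) for each list, from the replicated list (black, filled where the adjusted p was under 0.05) and from the longer lists of replicate 1 (orange) and replicate 2 (green), with the median (line) and central 95% (grey bar) of 10000 random lists matched on territory. The cortical glutamatergic lineage stands highest at 5.88 and olfactory receptors lowest at 0.0229.

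The longest H3K4me2 domains lay at genes of neural transcription factors and of a neural microRNA. Merging gave 27899 domains with a median length of 1377 bases, and the longest, of 35518 bases, covered Pou3f3, a POU factor of upper-layer neurons, and the lncRNA gene Pantr2, and overlapped the 5' part of the lncRNA gene Pantr1 (chromosome 1, 42679168 to 42714685). Its bases were covered at 96.7% by replicate 1 and 93.4% by replicate 2. Domains at Sox2 (31399 bases, chromosome 3), Foxg1 with Gm43517 (30747, chromosome 12), Nfib (29376, chromosome 4), Bcl11a with A830031A19Rik (29256, chromosome 11), Meis2 (27758, chromosome 2) and Nr2f2 (26565, chromosome 7) were also among the 10 longest. The other 3, of 33765 bases on chromosome 13 (83712740 to 83746504), 30583 on chromosome 3 (88198126 to 88228708) and 26385 on chromosome 7 (79495918 to 79522302), touched no protein-coding promoter and held Mir9-2, Mir9-1 and Mir9-3, the genes of a microRNA of neural progenitors, named here after these domains were seen. Each replicate covered between 84.3% and 97.9% of the bases of these 10.

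The longest 5% of domains were at least 4679 bases long and touched the promoters of 1504 protein-coding genes. They reached 17 of 20 occupied telencephalic patterning factors (adjusted exact p = 8.73e-14), 27 of 32 cortical (adjusted p = 6.07e-21), 25 of 34 GABAergic (adjusted p = 5.07e-17), 23 of 30 pan-neuronal (adjusted p = 1.56e-16) and 18 of 25 radial glia genes (adjusted p = 2.00e-12), against 10.2% of other occupied genes. Early response genes (10 of 17, adjusted exact p = 5.72e-06) and imprinted genes (7 of 21, adjusted p = 0.0145; Peg3, Nnat and Mkrn3 had most bases covered) were also higher by two-sided Fisher's exact tests. No other list passed; ribosomal protein genes had 3 of 77 (adjusted exact p = 0.176) and Hox genes 0 of 19 (adjusted p = 0.545). Merging peaks up to 3 kb apart turned the ribosomal value to the higher side, 22.1% (adjusted exact p = 0.00876), whereas among the longest 10% of domains the same list was called lower (6.49%, adjusted p = 0.00373). Merging at 3 kb also gave a call for astrocyte genes (40%, adjusted exact p = 0.0453), and among the longest 1% of domains early response genes had 0%. The call for imprinted genes was lost without merging (19.05%, adjusted exact p = 0.720), with replicated peaks above the median fold (11.1%, adjusted p = 0.722) and among the longest 1% of domains (4.76%, adjusted p = 1).

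**Figure D5:**
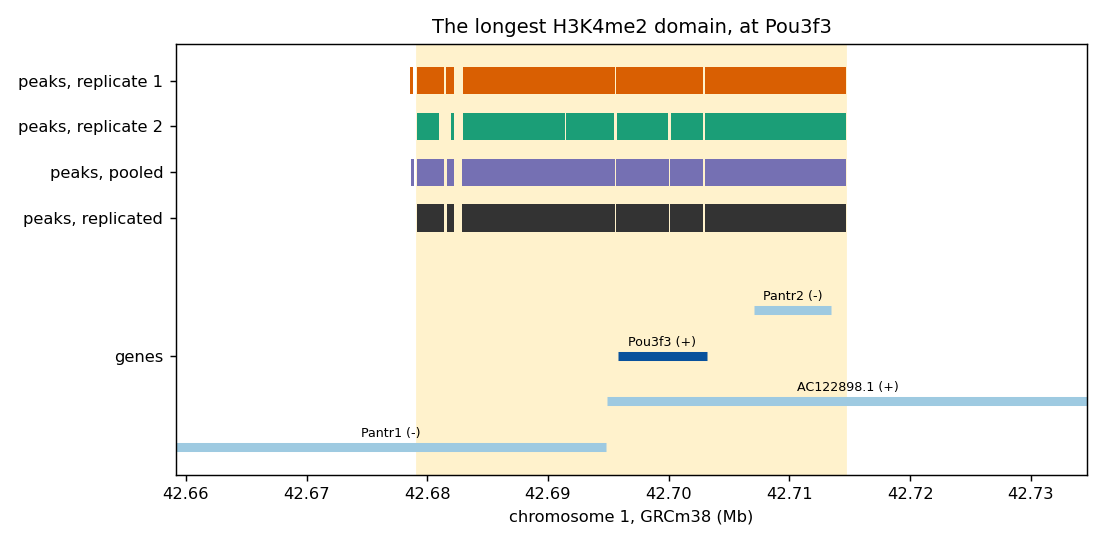
Map of the longest domain (shaded) on chromosome 1 (x axis, position in Mb, GRCm38), with the peaks of the 4 lists as bars and, beneath, the protein-coding gene Pou3f3 in dark blue and lncRNA genes in light blue, strand in parentheses. In the replicated list 6 peaks fill the domain from 42679168 to 42714685.

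The replicates differed at few promoters. A promoter peak was called in both at 14502 genes, in replicate 1 alone at 75, in replicate 2 alone at 145 and in neither at 7216. The genes of highest fold called in replicate 1 alone were Tsks (18.8 over control in that replicate), Lsp1 (17.4), Gm11444 (14.6), Dbx2 (14.6) and 4931409K22Rik (9.72), and in replicate 2 alone Cby3 (27.3), Ssc5d (22.4), B3gnt4 (21.5), Igfn1 (14.3) and Gsg1 (9.98). At all 10 a promoter peak of the one replicate overlapped a peak of the other that did not reach within 1 kb of a TSS of the gene, so these are not strong peaks of 1 replicate alone. Clustered protocadherins were the only list with at least 5 such genes, 6 in replicate 1 alone and 5 in replicate 2 alone, a split that did not differ from that of other genes (odds ratio 2.43, p = 0.191, two-sided Fisher's exact test, 1 list tested).

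Peak sequence differed from its surroundings. TSS peaks had a median GC content of 53.3% and a CpG observed/expected ratio of 0.559, against 44.3% and 0.187 in flanks outside peaks, and distal peaks had 50% and 0.379 against 44.6% and 0.183. In the replicates' lists the peak values were 53.6 ± 0.0575% and 0.562 ± 0.00422 at TSS, and 49.8 ± 0.0152% and 0.354 ± 0.00395 at distal sites (SD, n = 2), so the gaps to the flanks exceeded the spread between replicates.

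Distal peaks were searched for words bound by factor families of the developing brain. TAATTA, the core bound by homeodomain factors such as Dlx and Lhx proteins, was found in 29.9% of 16423 distal windows and 25.05% of 28718 control windows, an enrichment of 1.32 over its rearrangements, above all 13 of them. ATTTGCA, of Pou factors, had 1.47 (98.3rd percentile of 359), GTTGCCA, a word of Rfx sites, 1.44 (98.3rd of 299) and TGCCAA, a word of NFI sites, 1.22 (95.8th of 119). GTTAAT, a word of Hnf1 sites included as a control from other tissues, passed the same level with 1.27 (96.6th of 59). The E-box CAGCTG had 1.30 (92.7th) and the E-box CATATG 0.785 (4.76th), and the Gata word AGATAA (0.986) and the Hnf4 word CAAAGTC (1.04) stayed near 1. Of the other words, TTCAAAG of Tcf/Lef factors had 1.25 (89.7th), and CAGATG, ACAATG, ACAAAG, TGACTCA, CATTCC and GGAAGT lay between 0.980 and 1.04. With peaks above the median fold alone, TAATTA and ATTTGCA remained above the 95% level and the other 3 did not. For TAATTA the level is coarse: with 13 rearrangements, the word passes only by standing above all of them. TGCCAA also fell under it in windows of 200 bases on either side of the summit (94.96th), and CAGCTG passed it with the pooled list and with control windows 10 kb away (95.1st in both).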

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

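No result met the conditions set for a closer look, since the single group has 2 samples, too few to single out either; 3 patterns were weighed instead, and the only test of this part chosen after the results were seen is the one on peaks that overlap the other replicate.

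Hox genes, which pattern the axis behind the forebrain, had promoter peaks at 19 of 39 genes, with a median of 856 covered bases. CpG-rich promoters that carry peaks whatever the gene would give the share of other such promoters. Hox genes lay far under it, at 13 of 24 against 98.9% (two-sided Fisher's exact p = 8.38e-16). That argues against CpG content alone deciding which Hox promoters carry a peak, but it cannot tell why those 13 have one. For cells of the posterior neural tube in the dissected tissue, the value fixed beforehand was met on the side against it: posterior factors had 2.62 distal peaks per gene and telencephalic ones 4.65 (two-sided permutation p = 0.0345). That condition was judged wrong after the value was seen, because posterior factors also stood above territory-matched genes (2.62 against 0.885, adjusted permutation p = 0.00195) and a minority of posterior cells could give fewer distal peaks than the main tissue. A minority of posterior cells and a weak mark in forebrain cells therefore cannot be told apart here, and no biological explanation was tested, since the design has 1 group.

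Peaks covered more bases at occupied promoters of 5 lists of telencephalic, progenitor and neuronal genes, with medians from 5259.5 to 6762.5 bases. Longer CpG-rich sequence at these promoters did not account for the whole of it: against genes matched on CpG number within 5 kb, 5 of 5 lists stayed higher, although the matched median rose to 3750.5 bases for telencephalic factors, so part of their width may go with CpG content. Matching on several annotated start sites within the window left 5 of 5 higher, with matched medians from 2296 to 2420 bases. Matching on the promoter's highest fold, for stronger enrichment giving wider called peaks, also left 5 of 5 higher, with matched medians from 2358 to 2543 bases. Every p was 0.0002, the smallest that 10000 random lists can give; matching on these properties together was not tried, and no biological explanation was tested.

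Promoter peaks were called in 1 replicate alone at 220 genes. Peaks near the calling threshold would lie low in their list, and 94.5% of these promoters had their strongest peak below the median fold of that replicate's list, against 4.199% (replicate 1) and 3.21% (replicate 2) of the promoters called in both. That meets the value fixed beforehand, but the test is set aside: at least 99.9% of the peaks in each of the upper 5 ranks by fold are shared between replicates, which nearly fixed its outcome, and the median folds (7.59 and 6.72) do not mark the threshold. Whether these peaks lie near it is left open. Peaks that reach the promoter window in 1 replicate only would overlap a peak of the other replicate, and 6.82% did, so that explanation is argued against for most of them. The 10 genes named for their high fold, such as Tsks and Cby3, are exceptions. At all 10 a promoter peak overlapped a peak of the other replicate that did not reach the window, which is what this explanation describes. Their choice by fold nearly fixed that overlap, since peaks of high rank are shared. A difference in depth between the libraries stays open, since no counts were given, and no biological explanation was tested.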

How the results depend on the processing

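No alternative of this part was added after the results were seen, and the cause of the shifts given here was not tested except where the alternative's construction shows it. No paired analysis was possible because the series has 1 group and no test between groups. The unknown depth limits every statement on regions without a peak, and weak peaks are the least shared between replicates. The share of pooled peaks in the replicated list was 74.7% by equal position and by 50% of both intervals, which says nothing on its stability, since every replicated peak has the same position in the pooled list. The numbers of promoters called in 1 replicate alone stayed within 1.5 times. Over lists and words, 814 of 890 comparisons with an alternative kept their side of the threshold without reversing a call (62 of them, not called under either setting, changed direction), 43 lost and 23 gained a call, and 10 reversed. Calls held under every setting run for 9 of 13 lists in breadth, 8 of 11 in distal peaks, 5 of 7 in broad domains and 2 of 5 words (TAATTA and ATTTGCA). The per-gene values of named genes differed by less than 1 SD of the replicates in 490 comparisons, and the other 1564 were counted as moved. Where both replicates gave the same value there was no spread, so even an unchanged value was counted as moved. Meis2, with 10001 covered bases in the replicated list and in each replicate, is such a gene. The 1564 therefore does not tell how many values changed.

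The share of peaks in common between replicates was 84.7% (replicate 1) and 81.1% (replicate 2) at 1 base of overlap, 69.5% and 67.6% at 50% of both intervals, 84.3% and 81.9% at a −log10 q of at least 2, and 97.1% and 93.4% above each list's median fold. With 1 replicate's list in place of the replicated list, TSS peaks were 45.8 to 47.1%, intergenic peaks 20.1 to 20.6%, and occupancy 66.4 to 66.8% of all, 98.8 to 98.9% of CpG-rich and 40.6 to 41.1% of CpG-poor promoters. The gaps between peaks and flanks were then 9.12 to 9.23 points of GC and 0.373 to 0.380 of CpG observed/expected at TSS, and 5.09 to 5.18 and 0.172 to 0.177 at distal peaks. With the pooled list, TSS peaks were 42.0%, intergenic peaks 22.5%, occupancy 67.1%, 98.9% and 41.7%, and the gaps 8.79 and 0.360 at TSS and 4.98 and 0.165 at distal peaks.

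With replicated peaks above the median fold, TSS peaks were 82.1% and intergenic peaks 8.25%, occupancy 60.99%, 95.9% and 33.1%, and the gaps 9.29 and 0.390 at TSS and 7.97 and 0.315 at distal peaks. In that setting 3 lists had lower breadth, 2 words passed the 95% level, and posterior neural factors reversed to 50% occupied. A TSS window of 500 bases gave 39.9% TSS and 22.3% intergenic peaks and 65.9% and 39.6% occupancy of all and of CpG-poor promoters, and one of 2 kb gave 58.2%, 19.8%, 67.2% and 41.9%, with 98.9% of CpG-rich ones.

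In occupancy 13 of 21 calls held under every setting other than CpG-rich promoters alone. In that setting, where nearly all promoters are occupied and little room is left for a higher call, 0 lists were higher and 2 lower; erythroid, liver, muscle, vomeronasal and protocadherin genes, with at most 3 members left, reversed to 100%, and posterior factors (94.7%) and ribosomal genes (98.5%) to the lower side. Microglial, olfactory receptor and keratin genes have no CpG-rich promoter and could not be tested in it. Among CpG-poor promoters 9 lists were higher and 6 lower; erythroid, heart, muscle, epithelial, Hox and germline genes lost their calls. With all protein-coding genes as background, Hox, germline, heart and meningeal genes lost their calls of lower breadth. A breadth window of 2 kb gave 11 lower lists, no territory matching 4 with fewer distal peaks, and the longest 10% of domains 1 lower, ribosomal genes (6.49%). Merging at 3 kb reversed ribosomal genes to 22.1% in broad domains, and the longest 1% of domains, a smaller set, left early response genes at 0%.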

Other observations

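All values and tests of this part were chosen after the results were seen.

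Families of genes that share a symbol stem were compared by breadth. Among 476 families with at least 5 occupied members, 14 were covered over more and 13 over fewer bases than random occupied genes (two-sided permutation tests, adjusted over the 476). Zic genes, zinc finger factors of the neural plate and its derivatives, had a median of 8882 bases within 5 kb of the TSS and Sox genes 6145 (both adjusted permutation p = 0.00952). Non-clustered protocadherins (symbol stem Pcdh) had 6371 and the Wnt receptor genes Fzd 5410 (both adjusted permutation p = 0.00952), while the corepressor genes Tle had 6052 (adjusted p = 0.0251) and the Notch target genes Hes 5097 (adjusted p = 0.0317). The chromatin genes Cbx had 5391.5, histone genes 4664 and Bcl genes 4854 (each adjusted permutation p = 0.00952), Mllt genes 5847 (adjusted p = 0.0212), the glutamate receptor genes Grik 5264 (adjusted p = 0.0436) and Slitrk genes 4928 (adjusted p = 0.0439). Whether the wide families share a function was not tested. The random genes were not matched on neighbouring start sites, and genes within 5 kb of each other count the same covered bases. Histone genes can lie that close, as do Hist1h2ao at 21810465 and Hist1h2bq at 21810197 on chromosome 13, both without a promoter peak. The width of clustered families may therefore come from their neighbours, and their members are not independent. The Pax family was narrow by its median, with 827.5 bases over 8 occupied genes (adjusted permutation p = 0.0136), and had 3.78 distal peaks per gene over its 9 genes. Pax6, a member of the telencephalic and radial glia lists, was wide instead, with 5936 bases (5706 in replicate 1 and 6465 in replicate 2). Prss (750 bases, adjusted permutation p = 0.0178) and Alox genes (747, adjusted permutation p = 0.0286) were narrow with 0.333 and 0.714 distal peaks per gene. The distal counts of these families were not tested.

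All 3 loci of Mir9 lay in the 10 longest domains, at ranks 2, 5 and 10. The loci of Mir124a, a microRNA abundant in neurons, lay in domains of 14469 bases (Mir124a-2, chromosome 3, rank 43), 10742 bases (Mir124a-1, chromosome 14, rank 101) and 8706 bases (Mir124a-3, chromosome 2, rank 185), all within the longest 5%. Of 266 annotated microRNA genes overlapping a domain, 75 lay in the longest 5%, and no test was made of that number. It cannot be read against 5%, since a longer domain can overlap more genes by its length and several of these genes share the same domain.

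Within the clustered protocadherins, a family in which neurons choose among alternative promoters, occupancy was uneven. The 5 C-type genes (Pcdhac and Pcdhgc) were all occupied and 8 of 12 Pcdhga genes were, against 1 of 11 Pcdha, 1 of 22 Pcdhb and 0 of 6 Pcdhgb genes. Within the Hox clusters, promoter peaks were found at 5 of 11 Hoxa, 3 of 10 Hoxb, 4 of 9 Hoxc and 7 of 9 Hoxd genes. These splits were not tested.

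CpG-rich promoters without a peak were rare, 115 of 9740. A candidate explanation is repeated sequence in which reads cannot be placed: 46.1% of them (53 promoters) had at least 50% of their 32-base words elsewhere on the chromosomes, against 0.758% of those with a peak (two-sided Fisher's exact p = 3.39e-73). The share was 44.8 to 46.2% among the promoters without a peak in the replicates' and pooled lists, and the 62 others had at most 28.2% repeated words. This share lies under the 50% set as counting against repeats, but that level was set after the results were seen. A binomial interval (37.3 to 55.2%) spans 50%, although all such promoters were counted, and the lists compared come from the same libraries. The reading was changed more than once, and no verdict is drawn on these gaps as a whole. By this measure repeats do not cover the 62 others. For the 53 repeated promoters the explanation stays open. For the 11 Hox and 4 germline genes among the 115 the explanation is argued against, with 0% repeated, a test added once that breakdown had been seen. A further 47 promoters were neither repeated nor in these fixed lists, and their lack of a peak was not explained by any test here. The fixed lists are not complete, so the 47 can hold genes of the same kinds. They include Sycp2, and Gm28308, whose TSS at 52213339 on chromosome 6 lies beside that of Hoxa3 at 52213336. How many of the 47 are germline genes or lie in Hox clusters was not counted.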
